A study of Homo sapiens with 56 samples.

How the data were processed

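RNA from the PEO1 and PEO4 lines was profiled on 56 Affymetrix expression arrays, 28 per line, in 7 groups of 4 arrays each. Per the labels' protocols, cells spent 3 days in phenol-red-free medium with charcoal-stripped serum before the 3 h treatments, RNA came from a spin-column kit, and labelled RNA was made with a linear amplification kit. The titles of the PEO4 4OHT arrays carry the abbreviation Tam, which the series description defines as 4-hydroxytamoxifen, and these arrays were read as 4OHT on that basis. The drug doses also come from the series description. The labels do not say whether replicates were separate cultures, so the p-values here measure the spread between these arrays.

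The values the authors deposited are log2 expression values made by RMA, per the labels, with its version not given in the sources used here. They ranged from 2.178 to 14.331. Array medians lay between 7.401 and 7.484 in PEO1 and between 7.844 and 7.911 in PEO4, and the lines were taken from these values as normalized apart, which the labels do not state. RMA values hold no detection or background calls. Raw scanner files were not used here.

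The table held 22277 probe sets. Of these, 62 Affymetrix controls were set aside and used only as checks. Gene symbols came from the array's annotation table, in which 19064 probe sets had 1 symbol, 1043 had several and 2108 had none; the latter kinds were not tested as genes. Symbols were matched to RefSeq gene IDs for 19052 probe sets, and 0 symbols needed an update. For 4310 genes with more than 1 probe set the probe set with the highest mean over all arrays was kept, which left 11963 genes. Among named genes with other probe sets, 75 gene and comparison pairs were checked and 0 had another probe set called in the opposite direction. Sizes could differ widely between probe sets of a gene. In PEO1 those of GREB1 ranged from 0.21 to 1.97 with E2 and from -0.77 to 0 with ICI.

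Each line was fitted on its own with limma 3.58.1 in R 4.3.3, with 1 mean per group over 28 arrays, 21 residual degrees of freedom per gene and moderated variances without trend or robust options. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison were called. All adjusted p-values for genes are from limma. Differences of a response between lines were tested in 1 fit over 56 arrays. The median standard error was 0.063 in PEO1 and 0.071 in PEO4. Levels were not tested across lines: a planned limma test of PEO4 against PEO1 vehicle cells was not used, since the lines were taken as normalized apart, and genes differing by at least 4-fold were counted and described instead.

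Fixed lists, 23 in number, were tested with limma's camera with an inter-gene correlation of 0.01, adjusted over the lists of each comparison. They covered estrogen-induced and estrogen-repressed genes, steroid receptors, the insulin-like growth factor axis, G1/S and DNA replication, mitosis, ribosome biogenesis and MYC targets, immediate early genes, MAPK feedback, the circadian clock, cholesterol biosynthesis, the unfolded protein and integrated stress response, aryl hydrocarbon receptor targets, NF-kB and cytokines, the interferon response, p53 targets, epithelial, mesenchymal, Muellerian, drug transport and homologous recombination genes, and stromal and off-lineage hepatocyte and neural markers as controls. Some lists share members, such as STC2, IGFBP4, EGR3, KLF4, IER3 and FOSL1, so their results are not independent. Each list was also tested with a correlation estimated from the arrays and with fry. Over 21 comparisons this made 483 list tests, of which 89 passed with the preset correlation and 47 with both correlations. Genes called by E2 were tested as sets only in comparisons whose groups shared no array with that call, adjusted over all these set tests. The overlap of E2 calls was tested with Fisher's exact test.

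The named genes are the 10 called genes with the largest change in each direction for E2 and for the lines' levels, and 5 in each direction elsewhere, with up to 4 members of a list by smallest adjusted p. ESR1, PGR, GREB1 and IGFBP3 are given in the E2 and antagonist comparisons whatever their p. Of the genes this rule names, 2 are not reported here. The comparisons, tests, lists, naming rule and the alternatives other than leaving out the outlying arrays together were chosen before the data were examined. Intervals for the 4OHT and ICI difference are 95% intervals from the moderated t distribution, and genes beyond those 4 were chosen for them after their values were seen.

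Alternatives were a trend and robust variance, a filter dropping genes whose mean lay in the lowest 40 percent, all probe sets, quantile normalization, the replicate letter or number as a block, array weights, only the compared groups in the fit, and leaving out each array in turn. PEO4 0 h replicate 4 and ICI replicate 1 were also left out together, a choice made after their RNA quality was seen. Replicate labels were checked for pairing: residuals of arrays with the same label correlated at a mean of 0.021 in PEO1 (-0.402 to 0.341) and 0.045 in PEO4 (-0.451 to 0.423). For arrays with other labels the means were -0.007 and -0.013. Of 28 arrays per line, 11 in PEO1 and 15 in PEO4 correlated best with arrays of their own label. With 4 labels about 1 array in 4 would do so by chance, and both shares lay above that, the PEO4 share most. This excess was not tested. Labels were not treated as pairs in the main fits, though some pairing is not excluded, least of all in PEO4.

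The code was tested on simulated data with the same layout. Of 50 genes changed by 0.25 it recovered 50% in each line, of those changed by 0.5, 98% in PEO1 and 96% in PEO4, and of those changed by 1 or 2, 100%. The share of false calls was 7.45% in PEO1, above the nominal 5%, and 4.95% in PEO4. A shifted list of 20 genes gave a camera p of 6.51e-13 and 4.26e-08, and of 200 random lists 0 and 1 fell under 0.05. Genes were simulated independently of each other, so this does not show the rate of false list calls among correlated genes. Tables were made with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.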

Results

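Transcript levels were measured on 56 Affymetrix arrays from PEO1 and PEO4, established high-grade serous ovarian carcinoma cell lines that express estrogen receptor alpha. Each line was kept for 3 days in hormone-deprived medium and then treated for 3 h with ethanol vehicle, 1 nM estradiol (E2), 1 µM fulvestrant (ICI), 1 µM 4-hydroxytamoxifen (4OHT), ICI with E2, or 4OHT with E2. Untreated cells were taken at 0 h. This made 14 groups of 4 arrays, 28 per line. Fulvestrant, named ICI here after its laboratory code, is an estradiol analogue with a long side chain at the 7-alpha position and is a full antagonist that destabilises the receptor. 4OHT, an active metabolite of tamoxifen, is a triphenylethylene that acts as a selective receptor modulator. Array medians lay between 7.401 and 7.484 (log2) in PEO1 and between 7.844 and 7.911 in PEO4. Replicate arrays correlated at 0.9923 or higher across genes, which are not independent replicates, the lowest value being among the PEO4 ICI arrays. The number of arrays limits the precision of every value below. Log2 fold changes are given ± SE, from limma over the 28 arrays of a line, with n = 4 arrays per group, and levels ± SD.

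ESR1, which encodes estrogen receptor alpha, stood at 11.32 ± 0.03 in PEO1 and 11.66 ± 0.06 in PEO4 under vehicle (SD, n = 4). PGR, the progesterone receptor gene and a classical estrogen target in breast cancer cells, lay between 3.12 and 3.89 in all 14 groups. E2 did not move it past the threshold. Its values were -0.18 ± 0.08 in PEO1 (adjusted p = 0.406) and -0.12 ± 0.08 in PEO4 (adjusted p = 0.757). RMA values carry no background calls, so whether PGR was detected at all cannot be stated. GREB1, an estrogen receptor target and cofactor, stood at 5.77 ± 0.20 in vehicle-treated PEO1 cells and at 8.51 ± 0.16 in PEO4 cells, although the lines were taken as normalized separately and such levels were not tested across them.

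The first question was which genes responded to estradiol within 3 h in PEO1. GREB1 rose most, by 1.97 ± 0.09 (3.91-fold, adjusted p = 5.12e-14), from 5.77 ± 0.20 to 7.74 ± 0.10. CA12, a membrane carbonic anhydrase, rose by 1.03 ± 0.05, the potassium channel subunit KCNF1 by 1.01 ± 0.06 and the adhesion molecule CADM1 by 1.00 ± 0.05, each with an adjusted p of 1.34e-12 or lower. Other large increases were IL12A (0.90), the amino acid transporter SLC7A2 (0.81), the mTOR inhibitor DEPTOR (0.80), OSBPL3 (0.77) and PLAT, tissue plasminogen activator (0.77). The decreases were smaller, led by GAS1, a growth arrest gene (-0.47 ± 0.07, adjusted p = 0.000113), TOX (-0.46), ARID5B (-0.46), and DLX2 (-0.43). The Wnt receptor FZD7 (-0.41), the cyclin CCNG2 (-0.39), EPHB3 (-0.38), FILIP1L (-0.37), PRAMEF12 (-0.36) and FRMD4B (-0.36) followed. limma called 250 genes at a Benjamini-Hochberg adjusted p under 0.05, 187 higher and 63 lower, and 1380 of 11963 genes had an unadjusted p under 0.05, where chance alone gives 598. With only the E2 and vehicle arrays in the fit the count was 159.

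In PEO1, 14 of the 35 measured genes of the estrogen-induced list rose with E2 and 0 fell (20 rose when adjusted over the list alone). Besides GREB1 and CA12 these included the cytokine signalling inhibitor CISH (0.62 ± 0.05) and the ADP-ribosyltransferase TIPARP (0.26 ± 0.03). The list moved up as a set (median 0.16, camera adjusted p = 6.85e-24, and 7.5e-08 with an estimated correlation). Of the 14 genes of the estrogen-repressed list, 5 fell, among them CCNG2, the urokinase gene PLAU (-0.31 ± 0.05) and SMAD6 (-0.28 ± 0.05), though the transcription factor KLF4 rose, by 0.50 ± 0.06. Adjusted over the list alone 8 fell and 1 rose, and the set moved down (median -0.10, adjusted p = 0.000387, and 0.00635 with an estimated correlation). The ribosome biogenesis and MYC target list moved up by a median of 0.06 (adjusted p = 6.64e-06, and 0.0383 with an estimated correlation). Past the threshold were 3 of 19 members, RRS1 (0.17), POLR3G (0.21) and POLR1B (0.21), and 7 over the list alone. Single members of other lists rose: the growth factor axis genes STC2 (0.42), IGF1R (0.24) and IGFBP4 (0.23), and the clock genes BMAL1 (0.67 ± 0.05, adjusted p = 1.59e-09) and PER2 (0.21). The early response gene EGR3 (0.70), MECOM, a zinc finger oncogene (0.49), and the drug efflux transporter ABCC1 (0.24) rose too. Of these, STC2, IGFBP4 and EGR3 are on the estrogen-induced list as well. The mineralocorticoid receptor gene NR3C2 fell (-0.27). ESR1 itself stood at -0.02 ± 0.04 (adjusted p = 0.927) and IGFBP3, an insulin-like growth factor binding protein, at -0.19 ± 0.05 (adjusted p = 0.0518).

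**Figure D1:**
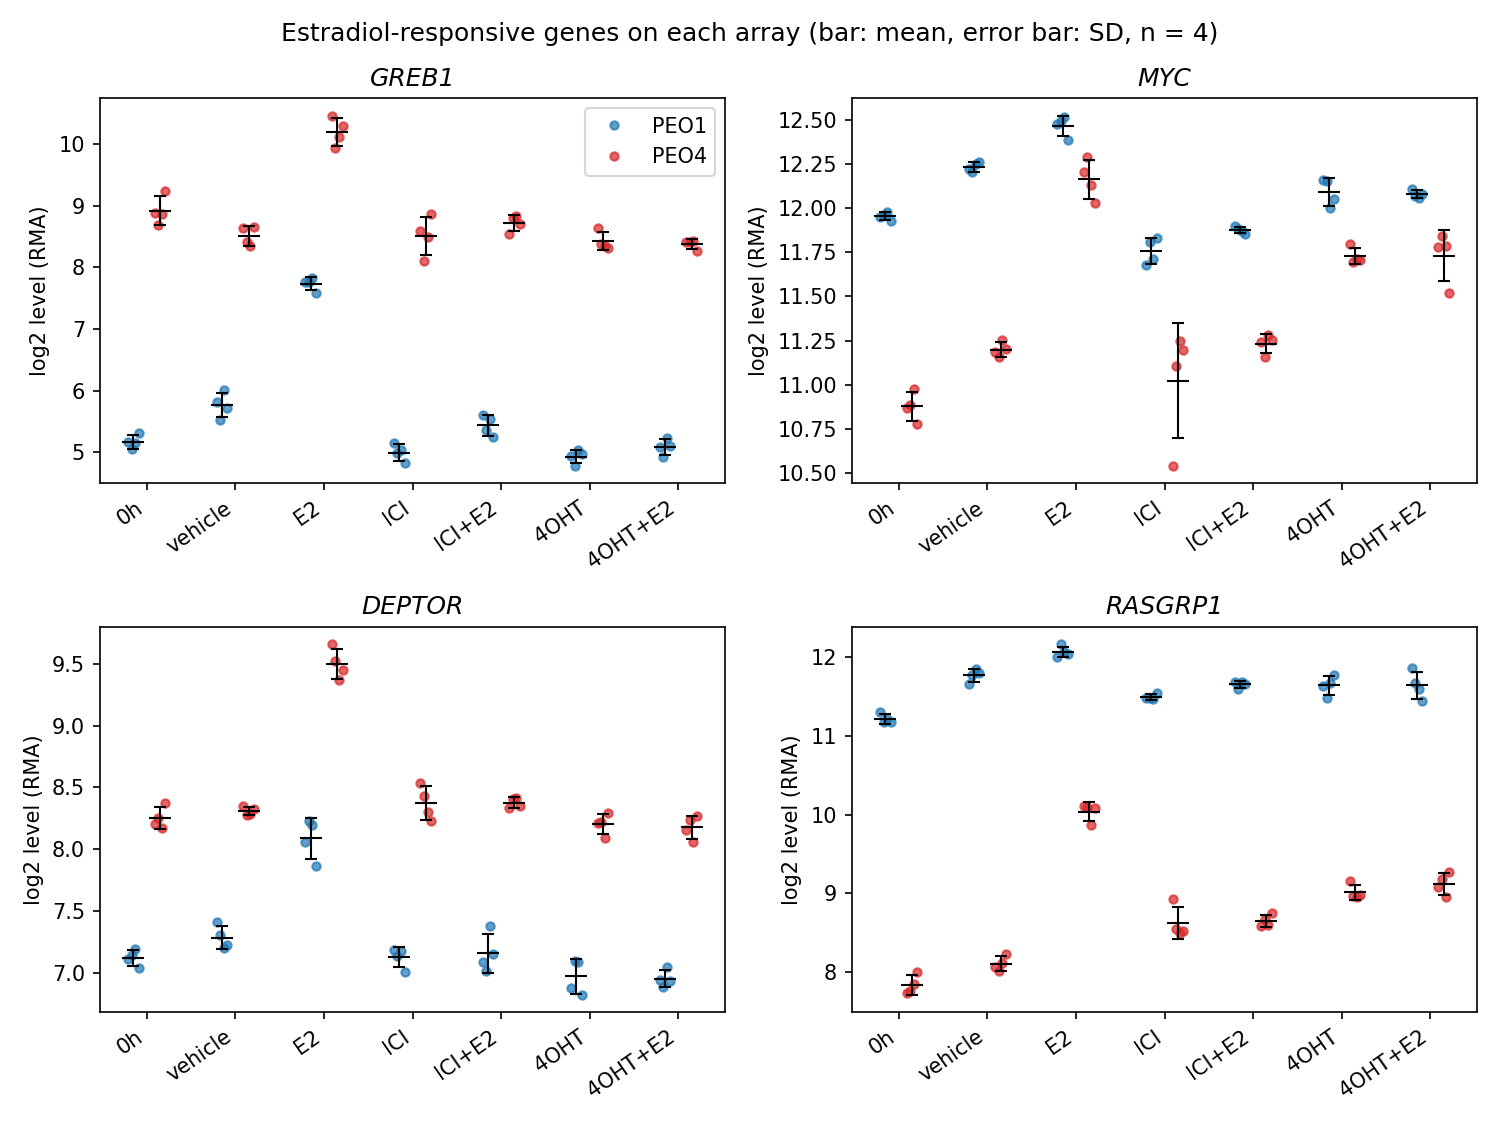
Log2 RMA level (vertical axis) of GREB1, MYC, DEPTOR and RASGRP1 on each array, by treatment (horizontal axis) and line, with bars for the mean and error bars for the SD (n = 4 arrays). GREB1 rose from 5.77 to 7.74 in PEO1 and from 8.51 to 10.20 in PEO4 with E2, and lay at 5.44 (PEO1) and 8.72 (PEO4) with ICI+E2; the lines were taken as normalized separately, so levels are to be compared within a line.

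In PEO4 the largest estradiol response was that of RASGRP1, a Ras guanine nucleotide exchange factor, which rose by 1.93 ± 0.09 (3.82-fold, adjusted p = 7.38e-15) from 8.10 ± 0.09 to 10.04 ± 0.12. GREB1 followed with 1.69 ± 0.13 (3.23-fold), KAZN, which encodes the desmosome-associated protein kazrin, with 1.35 ± 0.06, DEPTOR with 1.19 ± 0.07 and OLFML3 with 1.12 ± 0.07. OTUB2 (1.01), IL12A (1.01), PLCL2 (0.97), KLF4 (0.97) and the proto-oncogene MYC (0.96 ± 0.10, adjusted p = 1.55e-07) completed the 10 largest increases. ARID5B fell by 0.59 ± 0.08, the Wnt inhibitor DKK1 by 0.58 ± 0.09, the ephrin ligand EFNB2 by 0.51 ± 0.06 and its receptor family member EPHA4 by 0.50 ± 0.07. The other named decreases were KLF5 (-0.49), the matricellular gene CCN2 (-0.49), PDP1 (-0.48), PDZRN4 (-0.47), PCDH9 (-0.47) and RNF19A (-0.43). limma called 254 genes, 199 higher and 55 lower, with 1066 at an unadjusted p under 0.05. Without 0 h replicate 4 and ICI replicate 1, described below, the count was 400.

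In PEO4, 10 of 35 genes of the estrogen-induced list rose and 0 fell (15 rose adjusted over the list alone), with CA12 (0.69) and MREG (0.37) beside GREB1 and MYC. The set moved up by a median of 0.13 (adjusted p = 4.03e-18, and 4.99e-07 with an estimated correlation). The ribosome biogenesis and MYC target list moved up by a median of 0.11 (adjusted p = 4.6e-08, and 0.0157 with an estimated correlation). RRS1 (0.39 ± 0.04) and NOP16 (0.43 ± 0.05) led it, with 3 of 19 members past the threshold and 7 adjusted over the list alone. The mitosis list shifted down as a set (median -0.09, adjusted p = 0.000104, and 0.00125 with an estimated correlation) although 0 of 20 members passed limma's threshold on their own or over the list alone. CENPE had -0.13 ± 0.05 and KIF20A -0.09 ± 0.04. RNA quality differed between these groups, with ACTB 3' minus 5' values of 0.68 to 1.02 on the E2 arrays and 0.24 to 0.57 on the vehicle arrays, so this small shift is not separated from it. CCNG2 fell on the estrogen-repressed list (-0.31), where KLF4 rose, and that list did not pass as a set (median -0.04, adjusted p = 0.263). CYP1B1 and CYP1A1, xenobiotic and estrogen metabolising enzymes induced through the aryl hydrocarbon receptor, fell by 0.42 ± 0.07 and 0.36 ± 0.08. STC2 (0.46), PER2 (0.31), the death receptor TNFRSF10B (0.36), SOX17 (0.30), ABCC1 (0.30) and SPRY1 (0.32) rose, whereas IGFBP3 (-0.30 ± 0.07), DUSP5 (-0.35) and COL3A1 (-0.25) fell. ESR1 stood at 0.06 ± 0.06 (adjusted p = 0.957).

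The calls of both lines were then compared. Of the genes called higher by E2, 86 were called in both lines, where independent lists of these sizes would share 3.11 (odds ratio 87.6, Fisher's exact test, 2-sided p = 1.17e-108). Of those called lower, 14 were shared, against 0.29 (odds ratio 82.2, Fisher's exact test, p = 9.93e-21). In all, 0 genes were called in opposite directions. The E2 fits of the lines share no arrays. GREB1, CA12, DEPTOR, IL12A, KAZN, CADM1 and KLF4 were among the shared increases and ARID5B, CCNG2, EFNB2 and FZD7 among the shared decreases. The genes that E2 raised in PEO1 had a median change of 0.24 in PEO4 (176 of 187 above 0), and those it raised in PEO4 had a median of 0.17 in PEO1 (181 of 199 above 0). For these sets camera gave adjusted p = 1.35e-101 and 2.16e-87, and 7.6e-06 and 1.84e-07 with an estimated correlation.

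**Figure D2:**
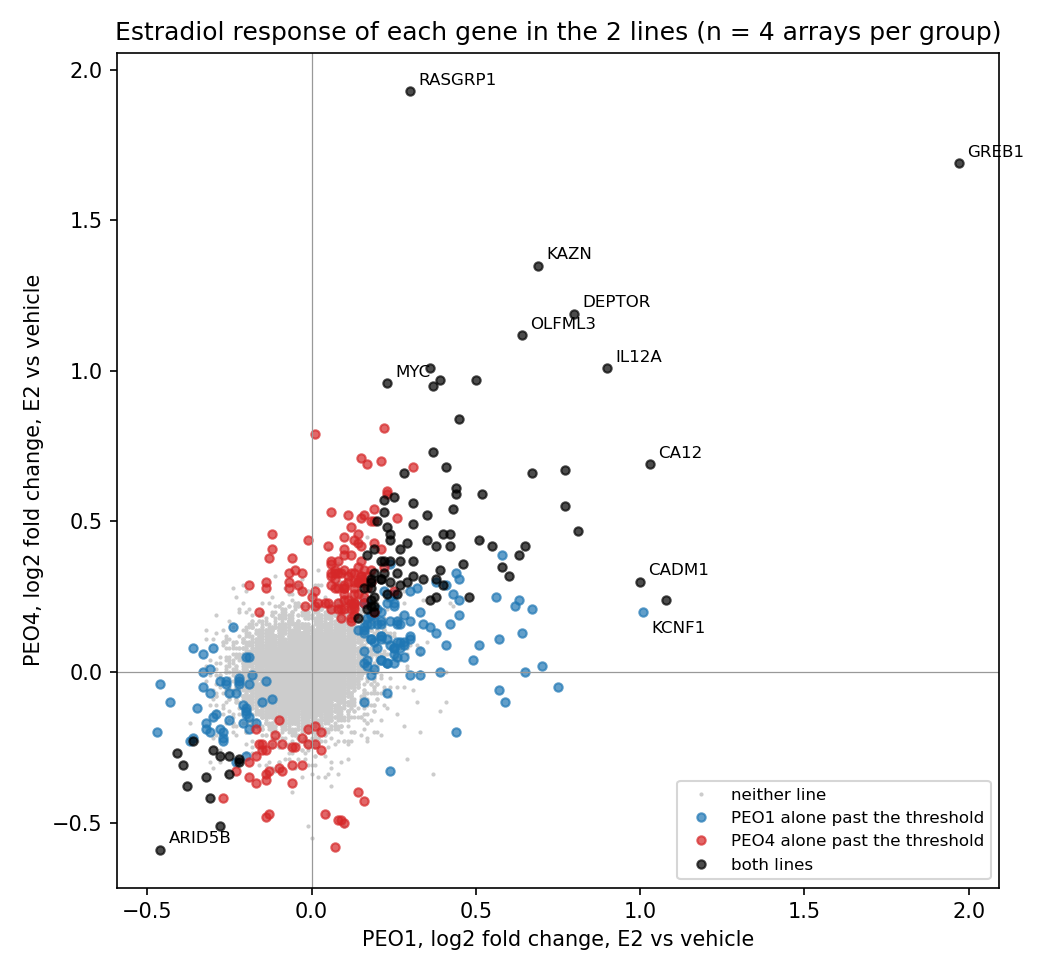
Log2 fold change of each of 11963 genes with E2 against vehicle in PEO1 (horizontal axis) and PEO4 (vertical axis), coloured by which line's limma test it passed, with n = 4 arrays per group. The 86 genes raised in both lines lie at the upper right, led by GREB1 (1.97 and 1.69), while RASGRP1 (0.30 and 1.93) lies far above the diagonal.

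The size of the response differed between the lines for 59 genes in a direct test of the difference, 34 with a larger and 25 with a smaller value in PEO4. The count was 112 with array weights, and over all probe sets 34 had larger and 37 smaller values. RASGRP1 differed most (1.64 ± 0.11, adjusted p = 1.38e-15), as it rose by 0.30 in PEO1 and 1.93 in PEO4. MYC (0.73 ± 0.11), KHDC1L (0.78), OTUB2 (0.65) and KAZN (0.65) had higher values in PEO4. KCNF1 (-0.82 ± 0.10), the sulfate donor synthase PAPSS2 (-0.80), CADM1 (-0.70) and PTGS2, cyclooxygenase-2 (-0.69), had higher values in PEO1. List members that differed were KLF4 (0.47) and RRS1 (0.22) upward and CISH (-0.39), CA12 (-0.34), EGR3 (-0.68), CCN2 (-0.57), EPHA4 (-0.60), BMAL1 (-0.47) and MECOM (-0.45) downward. GREB1 did not pass this test (-0.28 ± 0.16, adjusted p = 0.935), nor did ESR1 (0.07 ± 0.06), PGR (0.05 ± 0.12) or IGFBP3 (-0.11 ± 0.09). The difference in the mitosis list (median -0.09, adjusted p = 0.000642) and in the homologous recombination list (median -0.08, adjusted p = 0.00353) did not pass with an estimated correlation (adjusted p = 0.0792 for both). Of their members 0 passed limma's test, the smallest adjusted p being 0.205 for XRCC2.

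ICI alone lowered estrogen targets in PEO1. Against vehicle, GREB1 fell by 0.77 ± 0.09 (adjusted p = 2.81e-05), CBLN1, a cerebellin precursor, by 0.62 ± 0.07, CISH by 0.61 ± 0.05 and MYC by 0.48 ± 0.04 (adjusted p = 5.77e-08). On single arrays GREB1 lay at 5.049 to 5.322 at 0 h, 5.529 to 6.011 with vehicle and 4.823 to 5.148 with ICI. Its ICI range thus overlapped that at 0 h, and much of its fall is measured against a rise with vehicle. ID4, an inhibitor of DNA binding, fell by 0.45 ± 0.06, and PCDH9 (0.37) and DKK1 (0.28) rose. The estrogen-induced list moved down as a set, with a median of -0.05, and of -0.03 after quantile normalization. For it camera gave adjusted p = 2.3e-06, and 0.00148 with an estimated correlation. Past the threshold were 3 of 35 members, and 7 adjusted over the list alone. ESR1 (-0.08), PGR (-0.06) and IGFBP3 (0.06) did not pass. limma called 16 genes, 2 higher and 14 lower, with 558 at an unadjusted p under 0.05, fewer than the 598 chance alone would give. The count was 8 without vehicle A or ICI A, 9 without vehicle D or ICI B, 10 without vehicle B, 8 with only these groups in the fit, and 33 with array weights.

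In PEO4 ICI alone did not move the 4 genes followed throughout past the threshold: GREB1 stood at 0.00 ± 0.13 (adjusted p = 0.994), ESR1 at 0.08 ± 0.06, PGR at -0.14 ± 0.08 and IGFBP3 at 0.23 ± 0.07 (adjusted p = 0.112). RASGRP1, an E2-induced gene, rose by 0.52 ± 0.09 (adjusted p = 0.00882). OTOR (0.57), ENTPD2 (0.44), HAO2 (0.41) and ELK2AP (0.39) were also called higher, and TSPAN2 (-0.55), RNF32 (-0.44), GLRB (-0.44), the histone gene H4C8 (-0.41) and B3GALT2 (-0.39) lower. The estrogen-induced list did not pass (median 0.05, adjusted p = 0.992), with 0 members called over all genes or over the list alone. Nor did any other fixed list pass, the smallest adjusted p being 0.0894 for the immediate early and the NF-kB and cytokine lists. ICI replicate 1 stood apart. Its ACTB 3' probe set exceeded the 5' probe set by 3.41 (log2), against 0.52 to 0.92 on the 3 other ICI arrays. limma called 19 genes, 11 higher and 8 lower, with 2097 at an unadjusted p under 0.05. The count was 847 without ICI replicate 4, 6 without ICI 1, 10 without ICI 2 and 8 without ICI 3. It was 31 without vehicle 1, 1 without vehicle 2, 11 without vehicle 3 and 7 without vehicle 4. It was 9 without ICI 1 and 0 h 4, 0 with only these groups in the fit, 1 with dim genes left out and 2150 with array weights. This count is therefore not settled by these arrays.

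The difference of the ICI response between the lines was tested directly and passed for 12 genes, all with higher values in PEO4. They included RASGRP1 (0.79 ± 0.11, adjusted p = 1.84e-05), GREB1 (0.77 ± 0.16, adjusted p = 0.0257; 0.75 ± 0.17 and 0.0673 without PEO4 ICI replicate 1), CBLN1 (0.69 ± 0.11), KAZN (0.66 ± 0.08), MYBL1 (0.65 ± 0.10), CISH (0.55 ± 0.09) and KLF4 (0.35 ± 0.08). The vehicle level enters both responses, and GREB1 moved from 0 h to vehicle in opposite directions in the lines, without passing in PEO4. ESR1 (0.16 ± 0.06), IGFBP3 (0.17 ± 0.09) and PGR (-0.09 ± 0.12) did not pass. The estrogen-induced list differed as a set (median 0.08, and 0.05 after quantile normalization, adjusted p = 0.0197, and 0.046 with an estimated correlation), with 2 of 35 members past the threshold and 6 adjusted over the list alone. The MAPK feedback (median -0.05) and NF-kB and cytokine lists (median -0.09) passed with the preset correlation only, both with adjusted p = 0.537 with an estimated correlation. The count was 47 without PEO4 ICI replicate 4 and 747 with array weights.

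4OHT raised immediate early genes in PEO1 while lowering GREB1. The inducible heat shock gene HSPA6 rose by 1.63 ± 0.18 (3.09-fold, adjusted p = 2.34e-06), the AP-1 component FOSB by 1.62 ± 0.21, the anti-apoptotic BCL2A1 by 1.47 ± 0.14, the orphan receptor NR4A3 by 1.17 ± 0.15 and the chemokine CCL20 by 1.14 ± 0.15. GREB1 fell by 0.83 ± 0.09, PRR15L by 0.55 ± 0.05, TMEM100 by 0.53 ± 0.12 and CBLN1 by 0.48 ± 0.07. ESR1 fell slightly (-0.13 ± 0.04, adjusted p = 0.0245), as did IGFBP3 (-0.20 ± 0.05), and PGR did not pass (-0.09 ± 0.08). limma called 808 genes, 230 higher and 578 lower, with 2627 at an unadjusted p under 0.05. After quantile normalization of the arrays the split was 312 higher and 277 lower. The count was 384 without vehicle C, 449 without vehicle A, 465 without 4OHT B, 515 without 4OHT C and 249 with only these groups in the fit.

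Among the lists in PEO1, 12 of 22 immediate early genes rose with 4OHT and 0 fell, over all genes and over the list alone, including EGR3 (1.08 ± 0.13), ATF3 (0.85 ± 0.11), IER3 (0.75 ± 0.09) and FOSL1 (0.69 ± 0.09). The set moved up by a median of 0.31 (adjusted p = 1.4e-19, and 0.00238 with an estimated correlation). Of 18 NF-kB and cytokine genes 11 rose, 13 over the list alone, with CXCL2 at 1.00, CXCL3 at 0.75 and CXCL1 at 0.47. That set also moved up (median 0.35, adjusted p = 1.4e-19, and 0.000718 with an estimated correlation). Of 15 MAPK feedback genes 5 rose, 6 over the list alone, among them the phosphatases DUSP5 (0.68) and DUSP4 (0.54) (median 0.13, adjusted p = 6.44e-10, and 0.00305 with an estimated correlation). Of 20 mitosis genes 10 fell, 16 over the list alone, with the kinase AURKA at -0.29, the checkpoint genes BUB1 and BUB1B at -0.31 and -0.30 and MKI67 at -0.23. This set moved down (median -0.16, adjusted p = 2.18e-10, and 0.0201 with an estimated correlation). The G1/S and DNA replication list (7 of 24 lower, 13 over the list alone, median -0.11, adjusted p = 0.00182), with GINS2 (-0.22) and ORC1 (-0.28), did not pass with an estimated correlation (adjusted p = 0.0943). The circadian clock list (median 0.005, adjusted p = 0.0312), in which RORA (0.44), NFIL3 (0.18) and CRY1 (0.27) rose, lost its call with an estimated correlation (adjusted p = 0.0943). So did the unfolded protein and integrated stress response list (median 0.02, adjusted p = 0.0312, and 0.308 with an estimated correlation), in which DNAJB9 (0.24), ASNS (0.19) and PPP1R15A (0.38) rose and DDIT4 fell (-0.41). On these arrays 2 of 6 ribosomal RNA control probe sets were also higher with 4OHT (0.27 to 0.58), and 0 of 18 hybridization controls passed.

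**Figure D3:**
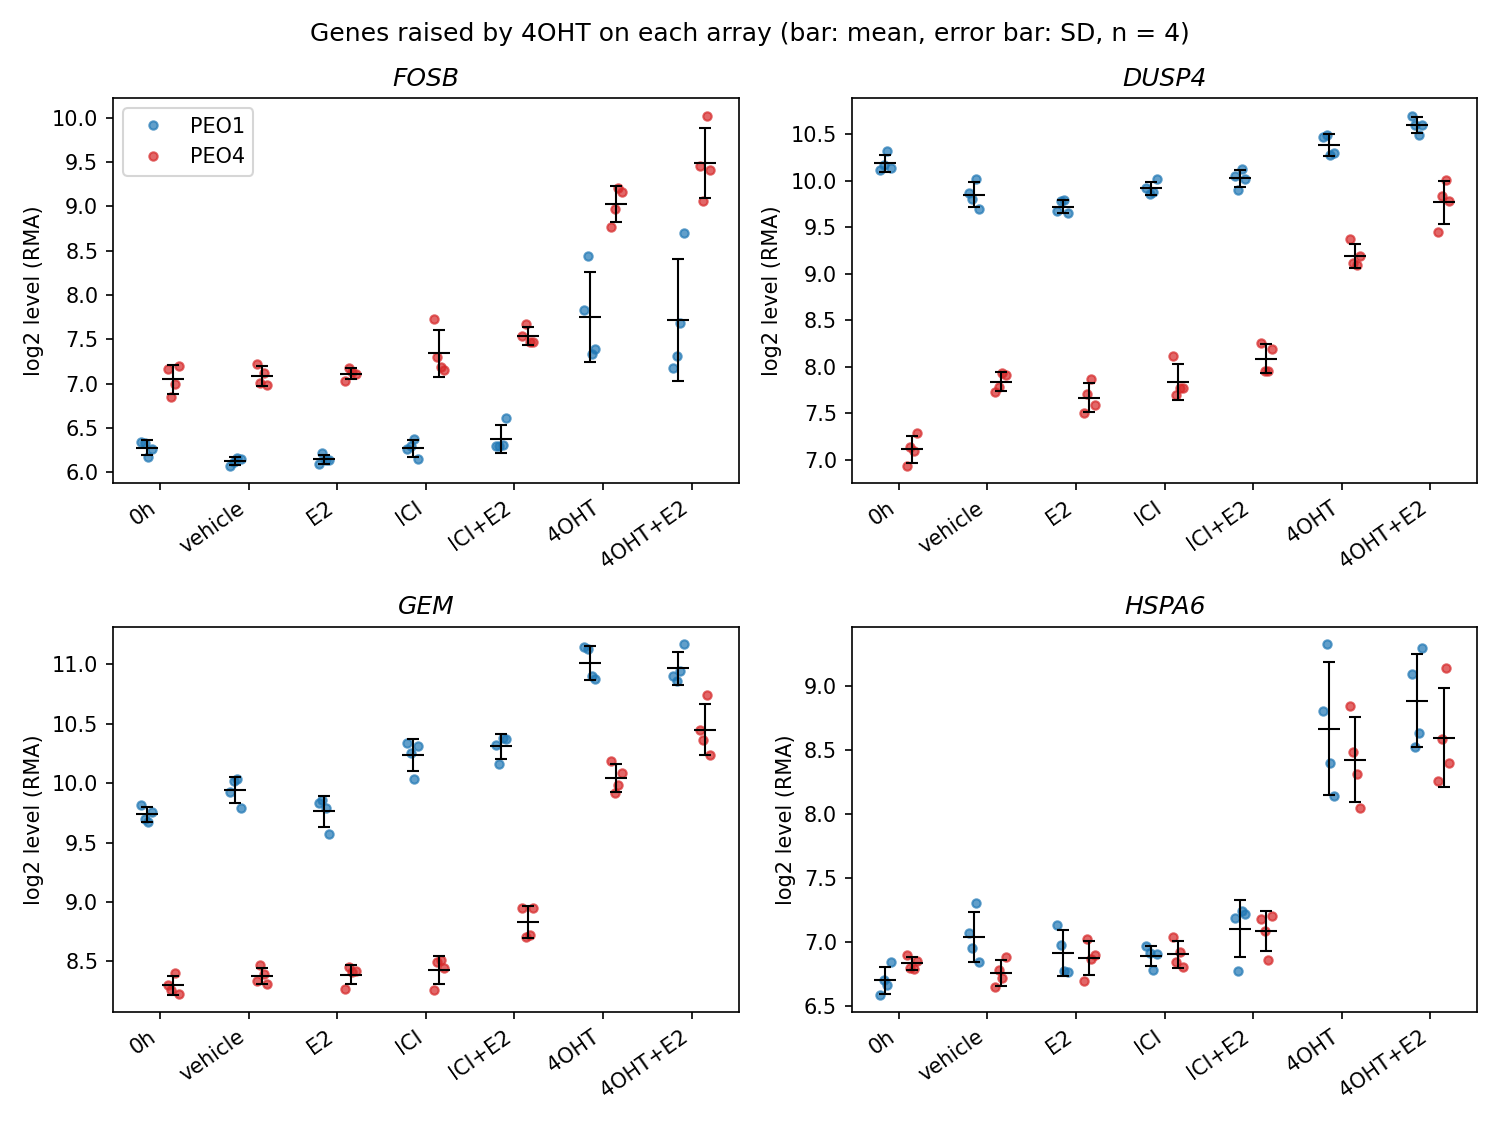
Log2 RMA level (vertical axis) of FOSB, DUSP4, GEM and HSPA6 on each array, by treatment (horizontal axis) and line, with bars for the mean and error bars for the SD (n = 4 arrays). HSPA6 lay at 8.67 and 8.89 in the 4OHT and 4OHT+E2 groups of PEO1 and at 8.43 and 8.60 in those of PEO4, against 7.10 or lower in every other group; the lines were taken as normalized separately.

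In PEO4, 4OHT raised FOSB by 1.94 ± 0.14 (3.84-fold, adjusted p = 3.56e-10), HSPA6 by 1.67 ± 0.14, the small GTPase GEM by 1.66 ± 0.08, the cell cycle regulator RGCC by 1.61 ± 0.11 and DUSP4 by 1.35 ± 0.11. TMEM100 (-0.78 ± 0.08), the cytokine receptor chain CSF2RB (-0.75 ± 0.09), the transcription factor MAF (-0.62), PRR15L (-0.58) and ZNF652 (-0.57) fell most. MYC, which ICI lowered in PEO1, rose by 0.53 ± 0.10 (adjusted p = 0.0011), and GREB1 did not pass (-0.09 ± 0.13, adjusted p = 0.788). ESR1 fell by 0.22 ± 0.06, IGFBP3 rose by 0.25 ± 0.07 and PGR stood at -0.09 ± 0.08 (adjusted p = 0.6). limma called 661 genes, 332 higher and 329 lower, with 2254 at an unadjusted p under 0.05. The count was 418 without vehicle 2, 1055 without ICI 1 and 0 h 4, 1033 with only these groups in the fit and 1977 with array weights.

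In PEO4, 11 of 22 immediate early genes rose with 4OHT (15 rose and 2 fell over the list alone), with IER3 at 1.21 and FOSL1 at 1.05 (median 0.31, adjusted p = 2.07e-15, and 0.000773 with an estimated correlation). The MAPK feedback list moved up (6 of 15 higher, 7 over the list alone, median 0.12, adjusted p = 2.01e-08). So did the NF-kB and cytokine list (6 of 18 higher, 7 higher and 1 lower over the list alone, median 0.19, adjusted p = 5.56e-07), with the NF-kB inhibitor TNFAIP3 at 0.53 and CXCL2 at 0.59. Both passed with an estimated correlation (adjusted p = 0.0104). The p53 target list moved up too, with 5 of 14 members higher (6 higher and 1 lower over the list alone), led by the cyclin-dependent kinase inhibitor CDKN1A (0.56 ± 0.10) and TNFRSF10B (0.40 ± 0.08). Its median was 0.10 (adjusted p = 0.000315, and 0.0104 with an estimated correlation). The ribosome biogenesis and MYC target list (median 0.07, adjusted p = 0.000387; 3 of 19 higher, 6 over the list alone), with RRP12 at 0.34 and NOP16 at 0.26, did not pass with an estimated correlation (adjusted p = 0.107). The estrogen-induced list (median 0.05, adjusted p = 0.0374, and 0.0994 with an estimated correlation) held 5 increases, among them HSPB8 (0.60), EGR3 (0.53) and MYC, and 1 decrease, PDZK1 (-0.30). CYP1B1 (-0.52) and CYP1A1 (-0.51) fell, as with E2. Among the control probe sets on these arrays, 6 of 18 hybridization controls were higher with 4OHT (0.17 to 0.37).

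The 4OHT response differed between the lines for 151 genes, 116 with higher and 35 with lower values in PEO4, and after quantile normalization 95 and 61. RGCC (1.09 ± 0.17), RASGRP1 (1.03 ± 0.11), the coagulation initiator F3 (0.82 ± 0.12), DUSP4 (0.82 ± 0.13), OTUB2 (0.80 ± 0.13), GREB1 (0.75 ± 0.16, adjusted p = 0.00963), MYC (0.67 ± 0.11), DUSP6 (0.47) and IGFBP3 (0.46 ± 0.09) had higher values in PEO4. Heme oxygenase HMOX1 (-0.67 ± 0.11), CSF2RB (-0.67), FRMD4B (-0.65), the antigen-presenting molecule CD1D (-0.64) and the phosphodiesterase PDE4D (-0.61) had lower values. ESR1 (-0.09 ± 0.06) and PGR (0.00 ± 0.12) did not pass. The mitosis (median 0.13), ribosome biogenesis and MYC target (median 0.12) and NF-kB and cytokine lists (median -0.15) passed with adjusted p = 0.00244, 0.00244 and 0.037, and none of them with an estimated correlation (adjusted p = 0.236, 0.236 and 0.399). After quantile normalization the mitosis median was 0.06. The count was 77 without PEO1 4OHT C, 93 without PEO1 vehicle C, 99 without PEO1 vehicle B or PEO4 vehicle 2, 294 without PEO4 ICI 1 and 0 h 4, and 473 with array weights.

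The antagonists were compared directly at the same dose, 1 µM, and the same time, whereas E2 was given at 1 nM. For the receptor target GREB1 the difference of 4OHT minus ICI was -0.06 in PEO1 (95% interval -0.25 to 0.13) and -0.09 in PEO4 (95% interval -0.35 to 0.17), so a difference of up to those bounds is not excluded. MYC was higher with 4OHT than with ICI in both lines, by 0.34 (0.25 to 0.42) in PEO1 and 0.71 (0.51 to 0.91) in PEO4, and KLF4 was higher by 0.53 (0.41 to 0.66) and 0.39 (0.28 to 0.49). Every PEO4 difference between the antagonists includes ICI replicate 1, with its ACTB 3' minus 5' value of 3.41. MYC stood at 10.539 on that array, 11.103 to 11.249 on the other PEO4 ICI arrays and 11.698 to 11.799 with 4OHT. The size of the PEO4 MYC difference thus rests partly on that array. ESR1 was lower with 4OHT in PEO4 (-0.30, -0.42 to -0.19) and did not pass in PEO1 (-0.05, -0.13 to 0.02), while IGFBP3 was lower in PEO1 (-0.27, -0.37 to -0.16) and did not pass in PEO4 (0.02, -0.12 to 0.17). PGR differed by -0.03 (-0.20 to 0.14) and 0.05 (-0.11 to 0.21), and CA12 by 0.09 (-0.01 to 0.20) and -0.06 (-0.19 to 0.06). The genes furthest apart were HSPA6 (1.78 ± 0.18), FOSB (1.48 ± 0.21), EGR1 (1.26 ± 0.18), BCL2A1 (1.21 ± 0.14) and CCL20 (1.14 ± 0.15) in PEO1. In PEO4 they were FOSB (1.68 ± 0.14), GEM (1.61 ± 0.08), RGCC (1.58 ± 0.11), HSPA6 (1.52 ± 0.14) and DUSP4 (1.36 ± 0.11), and all of these were higher with 4OHT. Lower with 4OHT were DACT1 (-0.55), TMEM100 (-0.52), GAS1 (-0.50) and the cholesterol exporter ABCA1 (-0.44) in PEO1, and TMEM100 (-0.82), CSF2RB (-0.60), TXNIP (-0.58 ± 0.04), the growth factor receptor FGFR2 (-0.51) and CYP1A1 (-0.47) in PEO4.

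Between the antagonists limma called 448 genes in PEO1, 202 higher and 246 lower with 4OHT (234 and 170 after quantile normalization), and 279 in PEO4, 150 higher and 129 lower, with 2319 and 1916 at an unadjusted p under 0.05. The immediate early list was higher with 4OHT in both lines, with 12 of 22 members (13 higher and 2 lower over the list alone) in PEO1 and 14 (17 higher and 1 lower) in PEO4. The medians were 0.34 and 0.32 (adjusted p = 1.02e-19 and 1.21e-30, and 0.00143 and 5.98e-06 with an estimated correlation). The NF-kB and cytokine list followed with medians of 0.32 and 0.29, and the MAPK feedback list with 0.09 and 0.19, each passing with an estimated correlation (adjusted p = 0.000444 and 0.000167, 0.00289 and 0.000167). The p53 target list was higher with 4OHT by 0.07 in PEO1 and 0.14 in PEO4 (adjusted p = 0.041 and 0.00194 with an estimated correlation). In PEO1 the mitosis list was lower (median -0.16, 8 of 20 members, adjusted p = 0.00998 with an estimated correlation). The estrogen-induced list was higher there (median 0.09, 7 of 35 members, adjusted p = 0.000444 with an estimated correlation), with EGR3 (1.11), MYC (0.34), CISH (0.23) and TIPARP (0.15) among the members. Also in PEO1, the G1/S, circadian clock and unfolded protein lists passed only with the preset correlation, as did the ribosome biogenesis list in PEO4. With an estimated correlation the adjusted p was 0.0776, 0.0555, 0.142 and 0.194. The PEO1 count was 220 without ICI A, 258 without 4OHT C, 280 without 4OHT B, 288 without ICI C and 107 with only these groups. The PEO4 count was 552 without ICI 4, 163 without 4OHT 1, 169 without 4OHT 2, 82 with only these groups and 2367 with array weights.

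Estradiol-induced levels were lower when ICI was present. In PEO1, GREB1 was lower by 2.30 ± 0.09 in ICI+E2 than in E2 cells (log2 change -2.30, adjusted p = 2.16e-15), KCNF1 changed by -1.13 ± 0.06, CISH by -1.07 ± 0.05, IL12A by -1.06 ± 0.09 and CA12 by -1.05 ± 0.05. IL6 (0.58), the prostaglandin receptor PTGER4 (0.57), DLX2 (0.56), GEM (0.54) and FZD7 (0.54) were higher. In PEO4, GREB1 changed by -1.48 ± 0.13, RASGRP1 by -1.39 ± 0.09, OLFML3 by -1.17 ± 0.07, DEPTOR by -1.12 ± 0.07 and KAZN by -1.09 ± 0.06, while DKK1 (0.90), GOLIM4 (0.71), RGCC (0.62), EFNB2 (0.61) and the membrane linker EZR (0.55) were higher. IGFBP3 was higher in both lines (0.20 ± 0.05 and 0.39 ± 0.07), and ESR1 (-0.07 and -0.12) and PGR (-0.07 and 0.03) did not pass. limma called 299 genes in PEO1 (116 higher, 183 lower) and 249 in PEO4 (73 higher, 176 lower), with 1191 and 1436 at an unadjusted p under 0.05. The PEO4 count was 155 without E2 replicate 2, 164 without ICI+E2 replicate 1, 407 without ICI 1 and 0 h 4, and 614 with array weights.

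The estrogen-induced list was lower with ICI+E2 than with E2 in both lines, with 17 of 35 members in PEO1 (19 over the list alone) and 11 in PEO4 (15). The medians were -0.18 and -0.14 (adjusted p = 5.22e-29 and 1.1e-11, and 1.32e-08 and 1.67e-05 with an estimated correlation). In PEO1 the estrogen-repressed list was higher (6 of 14 higher and 1 lower, 7 and 1 over the list alone, median 0.11, adjusted p = 2.31e-07, and 0.000158 with an estimated correlation), with PLAU at 0.45, the decoy receptor TNFRSF11B at 0.41 and KLF4 at -0.67. In PEO4 the mitosis list was higher as a set (median 0.08, adjusted p = 6.52e-05, and 0.000772 with an estimated correlation) with 0 of 20 members past limma's threshold. It rests on the same E2 arrays, whose ACTB 3' minus 5' values (0.68 to 1.02) lay mostly above those with ICI+E2 (0.48 to 0.79). Also in PEO4, the ribosome biogenesis (median -0.07), NF-kB and cytokine (median -0.09) and G1/S (median 0.05) lists passed only with the preset correlation (adjusted p = 0.238, 0.278 and 0.278 with an estimated correlation). To avoid shared arrays, genes called by E2 in one line were followed in the other: the PEO4 E2-higher genes had a median of -0.16 in PEO1 and the PEO1 E2-higher genes -0.21 in PEO4 for ICI+E2 against E2. Set against vehicle, those medians were -0.002 and 0.038 with ICI+E2, compared with 0.17 and 0.24 with E2 alone.

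With 4OHT present, E2 targets were lower and the 4OHT-induced genes higher than with E2 alone. In PEO1, GREB1 changed by -2.65 ± 0.09 (adjusted p = 6.46e-17), DEPTOR by -1.14 ± 0.08, CA12 by -1.07 and FLG, filaggrin, by -0.98, while HSPA6 (1.98 ± 0.18), NR4A3 (1.77), BCL2A1 (1.75), FOSB (1.57) and CCL20 (1.33) were higher. In PEO4, GREB1 changed by -1.82 ± 0.13, DEPTOR by -1.32 ± 0.07, OLFML3 by -1.17, the calcium-binding protein gene CASQ2 by -0.96 and ZNF124 by -0.93, while RGCC (2.50 ± 0.11), FOSB (2.38), DUSP4 (2.10), GEM (2.06) and NR4A3 (1.97) were higher. IGFBP3 was higher in PEO4 (0.56 ± 0.07), where ESR1 was lower (-0.25 ± 0.06). In PEO1 neither IGFBP3 (0.06 ± 0.05) nor ESR1 (-0.07 ± 0.04) passed. PGR did not pass in either line (0.09 and 0.10). limma called 1525 genes in PEO1, 510 higher and 1015 lower (596 and 661 after quantile normalization), and 686 in PEO4, 428 higher and 258 lower, with 3249 and 1931 at an unadjusted p under 0.05. The PEO1 count was 951 without E2 C, 997 without E2 B, 980 without 4OHT+E2 B and 497 with only these groups. The PEO4 count was 1474 with array weights. On the PEO4 arrays 15 of 18 hybridization controls were higher (0.18 to 0.46), 4 of 27 poly-A controls were lower (-0.33 to -0.29) and 1 ribosomal RNA probe set was higher (0.62). On the PEO1 arrays 2 of 6 ribosomal RNA probe sets were higher (0.31 to 0.53).

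Among the lists, the estrogen-induced genes were lower with 4OHT+E2 than with E2 (11 of 35 lower and 2 higher in PEO1, 8 and 3 in PEO4; 13 and 2, and 9 and 3, over the list alone). The medians were -0.10 and -0.08 (adjusted p = 3.07e-05 and 0.000862, and 0.0046 and 0.0088 with an estimated correlation). After quantile normalization they were -0.06 and -0.09. In PEO1 the estrogen-repressed list was higher (median 0.07, adjusted p = 0.00194, and 0.0185 with an estimated correlation), with EFNA1 at 0.34. The NF-kB and cytokine list was higher in both lines, 12 of 18 members in PEO1 (13 over the list alone) and 10 in PEO4, at medians of 0.32 and 0.40 (adjusted p = 0.00384 and 0.000347 with an estimated correlation). Members included IL6 at 0.77 and NFKB1 at 0.46 in PEO1 and CXCL2 at 1.11 and CCL20 at 1.18 in PEO4. The MAPK feedback list was higher too (medians 0.12 and 0.33, adjusted p = 0.0209 and 0.000347 with an estimated correlation). The immediate early list was higher by 0.18 and 0.38; with an estimated correlation it passed in PEO4 (adjusted p = 0.000188) and not in PEO1 (adjusted p = 0.063). In PEO1 the mitosis list was lower, with 12 of 20 members (15 over the list alone), AURKA at -0.31 and MKI67 at -0.30 (median -0.18, adjusted p = 0.0311 with an estimated correlation). The G1/S (9 of 24 lower), homologous recombination (5 of 12 lower, BRIP1 at -0.46 and BARD1 at -0.25) and ribosome biogenesis lists (4 of 19 lower) and the off-lineage hepatocyte and neural control list (0 of 14 past limma's threshold, median 0.09) passed in PEO1 with the preset correlation only. With an estimated correlation their adjusted p was 0.0575, 0.0595, 0.312 and 0.268. In PEO4 the p53 target (CDKN1A at 0.90) and mesenchymal lists (SNAI2 at 0.90, LOX at 0.28, FN1 at 0.27) likewise passed with the preset correlation only (adjusted p = 0.0679 and 0.0511 with an estimated correlation).

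The last drug question was whether E2 still changed expression when an antagonist was present. In PEO1 limma called 0 genes for ICI+E2 against ICI (380 at an unadjusted p under 0.05; 1 with a trend and robust variance, 2 with dim genes left out, 2 with the replicate letter as a block, 3 with array weights, and 1 without ICI replicate B). For 4OHT+E2 against 4OHT it called 0 as well (984 at an unadjusted p under 0.05; 0 with each of those 4 model settings and 5 without 4OHT replicate B). GREB1 stood at 0.44 ± 0.09 with ICI (adjusted p = 0.203) and 0.16 ± 0.09 with 4OHT (adjusted p = 0.677). With ICI the values of ESR1, PGR and IGFBP3 were -0.01, -0.19 and -0.05, and with 4OHT 0.04, -0.01 and 0.08. The genes that E2 raised in PEO1 still lay above 0 as a set in ICI+E2 against ICI, groups whose arrays are not in that contrast: 170 of 187 were positive, at a median of 0.07 (adjusted p = 3.72e-28, and 0.000542 with an estimated correlation). For 4OHT+E2 against 4OHT 135 of 187 were positive, at a median of 0.05 (adjusted p = 2.65e-07, and 0.0798 with an estimated correlation). Among the fixed lists in PEO1 with ICI, the estrogen-induced, ribosome biogenesis, immediate early, MAPK feedback, NF-kB and p53 target lists passed with the preset correlation at medians of 0.03 to 0.08, and none with an estimated one (adjusted p of 0.115 or higher).

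In PEO4 limma called 0 genes for ICI+E2 against ICI, with 1614 at an unadjusted p under 0.05. The count was 459 without ICI replicate 4, 1743 with array weights and 0 with a trend and robust variance, with dim genes left out or with the replicate block. GREB1 stood at 0.21 ± 0.13 (adjusted p = 0.434), ESR1 at -0.15, PGR at 0.05 and IGFBP3 at -0.14. For 4OHT+E2 against 4OHT it called 13 genes, 12 higher and 1 lower: NR4A3 (1.09 ± 0.15, adjusted p = 0.000533), the neuropeptide CALCB (0.81 ± 0.10), CCL20 (0.81 ± 0.15), BCL2A1 (0.79 ± 0.14), RGCC (0.66 ± 0.11), CXCL2 (0.61), DUSP4 (0.57) and the pioneer factor FOXA1 (0.55 ± 0.07) rose. The thrombin receptor F2R fell (-0.42 ± 0.08). GREB1 did not pass (-0.04 ± 0.13, adjusted p = 0.972), nor did ESR1 (0.03), PGR (0.07) or IGFBP3 (0.01). The NF-kB and cytokine list (median 0.14, 2 of 18 members, 8 over the list alone) and the immediate early list (median 0.10, 0 of 22 members, 5 over the list alone) were higher with adjusted p = 0.0322 and 0.0423 with an estimated correlation. The mitosis list was lower (median -0.05, 0 of 20 members, adjusted p = 0.0107 with an estimated correlation). The MAPK feedback (median 0.09) and epithelial lists (median -0.06) passed with the preset correlation only (adjusted p = 0.0943 and 0.362 with an estimated correlation). The genes that E2 raised in PEO4 had a median of 0.07 here (155 of 199 positive, adjusted p = 7.39e-10, and 0.149 with an estimated correlation) and of -0.007 in ICI+E2 against ICI (94 of 199 positive, adjusted p = 0.0831). The count of 13 was 21 without 4OHT 1, 5 without 4OHT 2, 4 without 4OHT 3, 30 without 4OHT+E2 1, 7 without 4OHT+E2 3 and 8 without 4OHT+E2 4. It was 32 without ICI 1 and 0 h 4, 4 with dim genes left out, 0 with only these groups and 79 with array weights. ACTB 3' minus 5' values were 1.74 and 1.07 on 4OHT+E2 replicates 4 and 3.

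Vehicle-treated cells at 3 h were compared with untreated cells at 0 h to show the change that came with time and vehicle. In PEO1, CBLN1 rose by 1.01 ± 0.07 (adjusted p = 5.94e-10), NAP1L3 by 0.91, the thiamine transporter SLC19A2 by 0.90, BCL2A1 by 0.89 and RGCC by 0.81, and RUFY2 (-0.73), the adaptor GRB7 (-0.68), DUSP5 (-0.67), the retinoic acid receptor RARB (-0.61) and DAAM1 (-0.61) fell. In PEO4, thrombospondin THBS1 rose by 1.56 ± 0.10 (adjusted p = 9.59e-12), LINC00472 by 1.13, DKK1 by 1.09, CYP1B1 by 1.06 and BAMBI by 1.05, and EGR1 (-1.24), the mTOR regulator DDIT4 (-1.12), DEPP1 (-1.05), the epithelial factor ELF3 (-1.03) and FRMD4B (-0.91) fell. ESR1 fell in both lines (-0.22 ± 0.04 and -0.28 ± 0.06), and PER2 rose in both (0.47 and 0.49). GREB1 rose in PEO1 (0.60 ± 0.09) and had the opposite sign in PEO4 without passing (-0.41 ± 0.13, adjusted p = 0.0502). IGFBP3 rose in PEO4 (0.46 ± 0.07) and did not pass in PEO1 (0.15 ± 0.05, adjusted p = 0.0674), and PGR did not pass in either line (0.02 and 0.04). limma called 889 genes in PEO1, 693 higher and 196 lower (501 and 335 after quantile normalization), and 754 in PEO4, 447 higher and 307 lower, with 2341 and 2288 at an unadjusted p under 0.05. The PEO1 count was 585 without vehicle C and the PEO4 count 1617 with array weights. On PEO4 0 h replicate 4 the ACTB 3' probe set exceeded the 5' probe set by 2.28, against 0.50 to 0.64 on the 3 other 0 h arrays. Of the control probe sets, 2 of 6 for ribosomal RNA were higher at 3 h in PEO1 (0.20 to 0.40) and 1 of 27 poly-A controls in PEO4 (0.29).

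Over these 3 h in PEO4, 10 of 18 NF-kB and cytokine genes rose, also over the list alone, with ICAM1 at 0.68, CXCL1 at 0.79 and IL6 at 0.58 (median 0.35, adjusted p = 1.45e-12, and 0.00104 with an estimated correlation). Of 15 MAPK feedback genes 8 rose and 1 fell (9 and 1 over the list alone), with SPRY2 at 0.51 and DUSP4 at 0.73 (median 0.23, adjusted p = 0.00766 with an estimated correlation). Of 22 immediate early genes 7 rose and 2 fell (9 and 2 over the list alone), with CCN1 at 0.74 and CCN2 at 0.77 (median 0.12, adjusted p = 0.0265 with an estimated correlation). Of 20 mitosis genes 5 fell (6 over the list alone), with BUB1B at -0.24 and KIF20A at -0.21 (median -0.12, adjusted p = 0.00104 with an estimated correlation). The aryl hydrocarbon receptor target list passed as a set (adjusted p = 0.0193 with an estimated correlation). Of its 8 members only CYP1B1 and TIPARP (0.34) were called, and the list was not tested without them. The ribosome biogenesis, p53 target and mesenchymal lists passed in PEO4 with the preset correlation only (adjusted p = 0.347, 0.137 and 0.137 with an estimated correlation). In PEO1, 7 of 24 G1/S genes rose (8 over the list alone), with CDC25A at 0.32 and CCNE1 at 0.28, and 6 of 19 ribosome biogenesis genes rose (8), with NOP2 at 0.23. Of 18 cholesterol biosynthesis genes 4 rose (9 over the list alone), with INSIG1 at 0.37 and IDI1 at 0.22, and 4 of 15 MAPK feedback genes fell (5 lower and 1 higher over the list alone), with FOSL1 at -0.50. Their adjusted p lay between 2.32e-05 and 0.00029 and was 0.0753 with an estimated correlation for all 4 lists. The stromal, endothelial and leukocyte marker list was lower in PEO1 (median -0.06, adjusted p = 0.0332, and 0.218 with an estimated correlation) with 0 of 18 members past limma's threshold, over all genes or over the list alone.

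**Figure D4:**
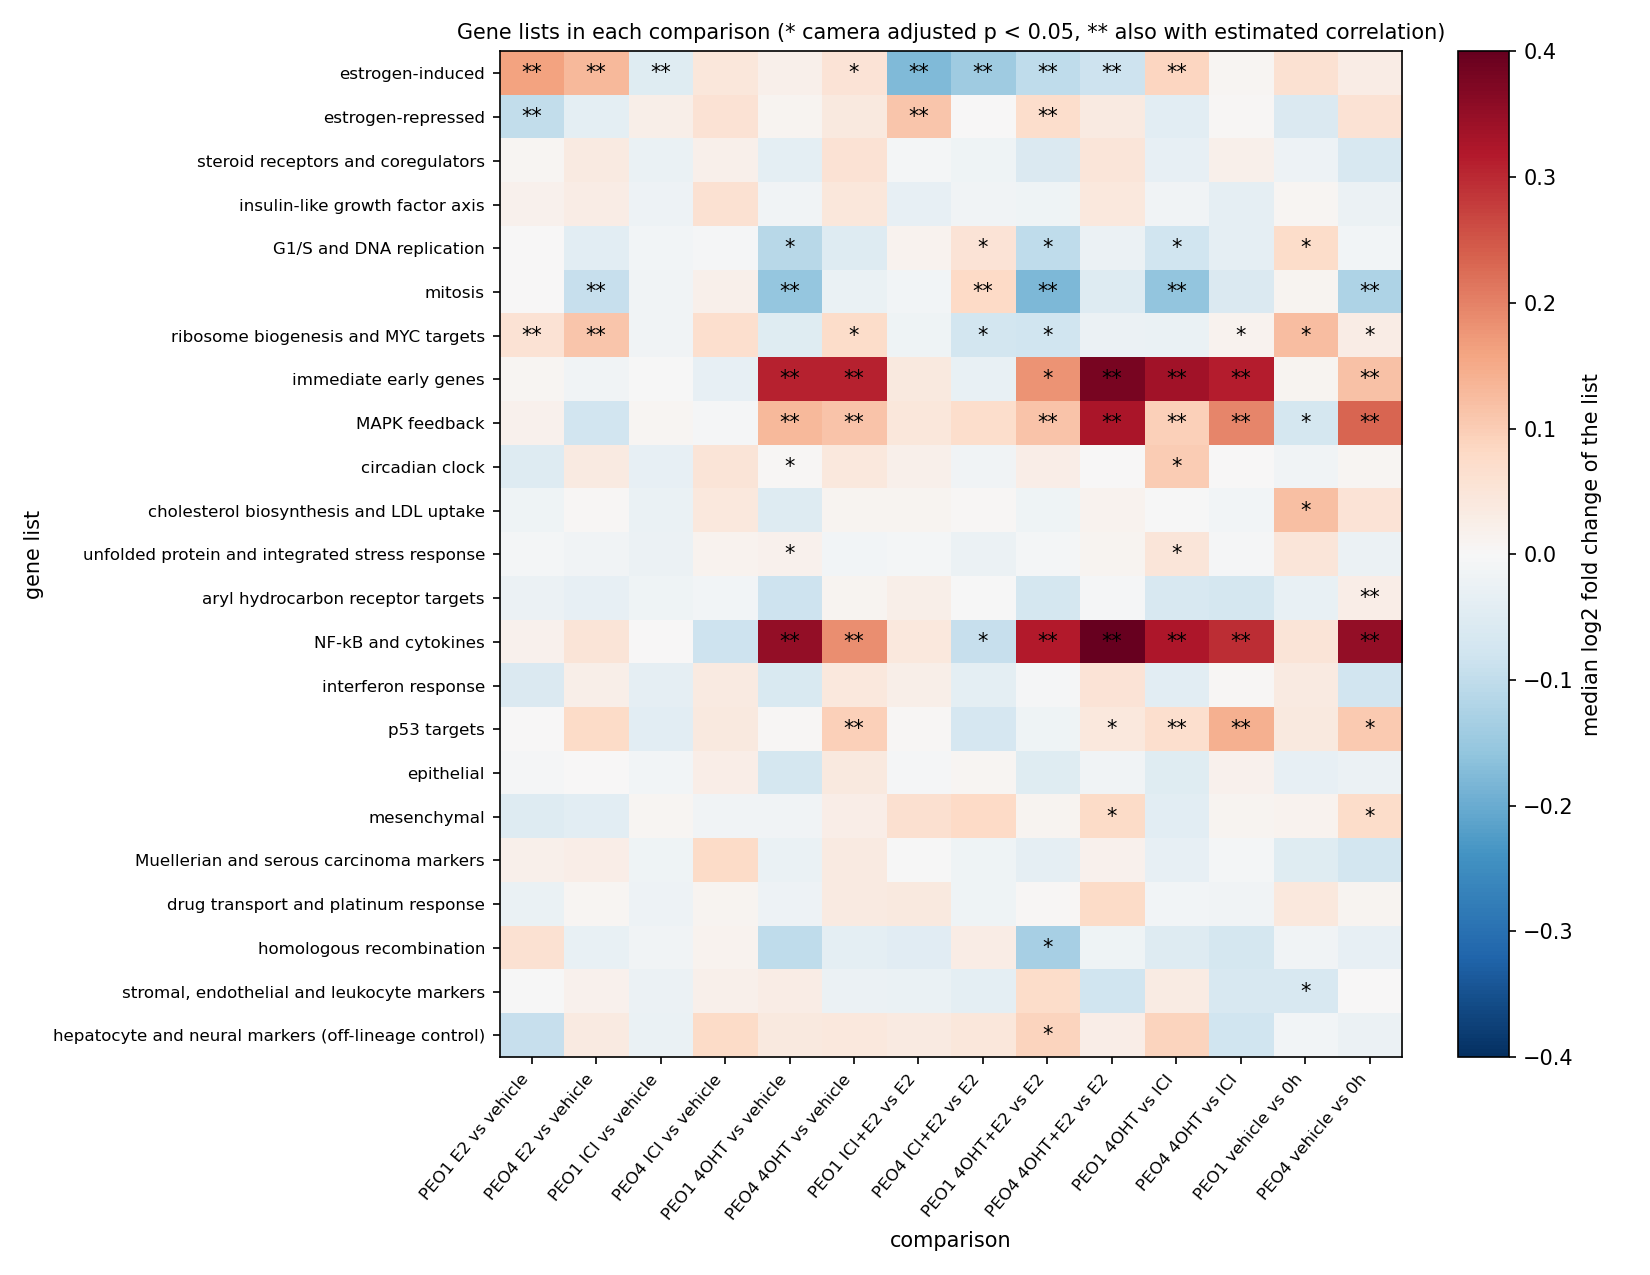
Median log2 fold change (colour scale) of each of the 23 fixed gene lists (vertical axis) in 14 comparisons (horizontal axis), with 1 star where camera's adjusted p was under 0.05 and 2 where it was also under 0.05 with an estimated correlation. The immediate early, MAPK feedback and NF-kB and cytokine lists are higher in each 4OHT comparison shown, up to a median of 0.40, and the estrogen-induced list is higher with E2 (0.16 and 0.13) and lower where an antagonist was added to E2.

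Other fixed lists gave no call in any of 21 comparisons. Their medians ranged from -0.06 to 0.06 for steroid receptors and coregulators (smallest adjusted p = 0.0531), -0.06 to 0.08 for the insulin-like growth factor axis (0.128), -0.08 to 0.06 for the interferon response (0.0531), -0.07 to 0.10 for Muellerian and serous carcinoma markers (0.0608) and -0.03 to 0.08 for drug transport and platinum response (0.306).

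Finally, vehicle-treated cells of the lines were set side by side without a test, since their arrays were taken as normalized separately. All genes together differed by a median of 0.448 in the deposited values and -0.018 after joint quantile normalization, so the following differences of PEO4 minus PEO1 are from the latter. RMA values carry no background calls, and several of the lower levels lay near the bottom of the scale, such as 2.82 for TRHDE in PEO4 and 3.57 for CEP15 in PEO1. Such differences are at best lower bounds, and neither their order nor the counts of 4-fold differences should be read as exact. Among the 10 largest upward values were AKR1D1, a steroid 5-beta-reductase (7.22, from 4.10 ± 0.10 to 11.32 ± 0.04), GPC1-AS1 (6.43), ZFPM2 (6.38), the secretoglobin SCGB2A1 (6.25), CEP15 (6.08), the calcium buffer CALB1 (5.42), and KCNJ4 (5.39). IFITM1 (5.07), ADAMTS1 (4.96) and the receptor kinase ERBB4 (4.88) were the others. Among the 10 largest downward values were PROM1, which encodes the stem cell marker CD133 (-8.17, from 12.89 ± 0.04 to 4.71 ± 0.12), RARRES1 (-6.30), TRHDE (-5.81), the collagen gene COL4A2 (-5.50), and the retinaldehyde dehydrogenase ALDH1A3 (-5.43). BEX1 (-5.24), NEDD9 (-5.22), the imprinted gene PEG3 (-5.13), S1PR1 (-4.96) and EPB41L3 (-4.89) were the others. After quantile normalization 286 genes differed by at least 4-fold, 134 higher and 152 lower in PEO4, and in the deposited values 363, 264 higher and 99 lower.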

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

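The tests below of why 4OHT raised early response genes, of the estrogen-induced list without 1 ICI array, of low 0 h values and of receptor activity over the 3 h of vehicle as the whole cause, and the breakdown of the draws between lines, were chosen after the results were seen.

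In groups of 4, a sample drew attention where its gap to the nearest other value took up most of the group's range, by Dixon's ratio. Chance gives about 1 such group in 20, and 9 of 146 groups had one. On the first axis of the residuals, PEO4 0 h replicate 4 scored 15.1 (others -6.8 to -3.6) and PEO4 ICI replicate 1 scored 20.8 (others -9.8 to -5.3). IGFBP3 stood at 9.87 on PEO4 vehicle replicate 2 (others 9.97 to 9.99), PDP1 at 8.75 on PEO4 vehicle replicate 4 (others 9.06 to 9.09) and GREB1 at 8.26 on PEO4 4OHT+E2 replicate 4 (others 8.41 to 8.43). RASGRP1 stood at 9.86 (others 10.09 to 10.11) and PCDH9 at 7.61 (others 7.33 to 7.37) on PEO4 E2 replicate 3, EPHA4 at 7.07 on PEO4 E2 replicate 2 (others 7.23 to 7.27), and CADM1 at 9.82 on PEO1 vehicle replicate C (others 9.68 to 9.70).

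Responses differed between the lines by a direct test, as PEO4 minus PEO1. For E2 59 genes passed, including RASGRP1 (1.64), KHDC1L (0.78), MYC (0.73), OTUB2 (0.65), KAZN (0.65), KCNF1 (-0.82), PAPSS2 (-0.80), CADM1 (-0.70) and PTGS2 (-0.69). For ICI 12 passed, including RASGRP1 (0.79), GREB1 (0.77), CBLN1 (0.69), KAZN (0.66) and MYBL1 (0.65). For 4OHT 151 passed, including RGCC (1.09), RASGRP1 (1.03), F3 (0.82), DUSP4 (0.82), OTUB2 (0.80), HMOX1 (-0.67), CSF2RB (-0.67), FRMD4B (-0.65), CD1D (-0.64) and PDE4D (-0.61). Outside the genes tested, E2 moved 31 probe sets without a single gene name in PEO1 and 19 in PEO4.

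4OHT raised 23 of 40 measured immediate early and NF-kB genes in PEO1 and 17 in PEO4, at medians of 0.52 and 0.53 among those that rose. Agonism that copies the E2 response at 3 h is argued against, since the larger of the lines' medians for the same genes with E2 was 0.07. That holds for the set and not for every member, as EGR3 rose with both drugs in PEO1. Receptor agonism on genes that E2 does not raise at 3 h was not tested. Low vehicle arrays are argued against too, since 4OHT+E2 against E2, which uses no vehicle array, gave 0.46 or more. A handling or labelling batch shared by the 4OHT arrays cannot be told apart from the drug, because every 4OHT array could share it. Of the control probe sets 8 passed in 4OHT against vehicle, 6 hybridization controls in PEO4 and 2 for ribosomal RNA in PEO1. More passed in 4OHT+E2 against E2 in PEO4, 20 of 62. Among them were 15 of 18 hybridization controls, all higher, with a median of 0.37 over the 18. In PEO1 2 of 62 passed in that comparison, both for ribosomal RNA. In PEO1 0 of 18 hybridization controls passed, and 2 ribosomal RNA probe sets also passed in vehicle against 0 h, without 4OHT. No biological explanation was tested beyond agonism that copies E2.

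The ICI response of the estrogen-induced list differed between the lines, PEO4 minus PEO1, by a median of 0.082 (0.049 after quantile normalization). The outlying PEO4 ICI replicate 1 as its cause is argued against, since a refit without that array gave 0.085 (adjusted p = 0.00112, and 0.00389 with an estimated correlation). The GREB1 difference went from 0.77 ± 0.16 to 0.75 ± 0.17 (adjusted p = 0.0673) and lost its call as the error grew. Whether PEO4 itself moved with ICI stays open. Genes that E2 raised in PEO1 had a median of 0.063 there, with an adjusted p of 0.561 with an estimated correlation, and this set was not tested between the lines. Without replicate 1 it was 0.022, within the SD of 0.027 of the 3 other arrays, so the outlying array and chance among the PEO4 ICI arrays both stay open for this value. ICI+E2 minus vehicle gave 0.038, but those cells also had E2. In PEO1 the same genes lay 0.073 higher with ICI+E2 than with ICI, which makes ICI+E2 a doubtful stand-in for ICI. In PEO4 they differed by -0.013, though that value rests on the ICI arrays in question, so neither decides. A biological cause of the difference between the lines is untested.

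In PEO1, genes that E2 raised in PEO4 rose from 0 h to 3 h of vehicle by a median of 0.157. Low 0 h values for all genes stay open: the median over all genes was 0.02, but normalization keeps it near 0 in every comparison, so it cannot decide. Receptor activity in the vehicle cultures stays open: genes that rose without an E2 call gave -0.011 with ICI+E2 against E2, but they were picked for lacking an E2 call, so this test cannot decide. Receptor activity over these 3 h as the whole cause also stays open, with a median of 0.081 for ICI minus 0 h, since 3 h of ICI need not remove all activity.

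Samples were regrouped in the 35 possible splits of 4 against 4, the real one included. In PEO1 only the real split gave as many genes (1 of 35) for E2 (250; highest other 1), ICI (16; 1), 4OHT (808; 1), ICI+E2 against E2 (299; 1), 4OHT+E2 against E2 (1525; 248), 4OHT against ICI (448; 0) and vehicle against 0 h (889; 2). The same held in PEO4 for E2 (254; 2), 4OHT (661; 1), ICI+E2 against E2 (249; 0), 4OHT+E2 against E2 (686; 8), 4OHT+E2 against 4OHT (13; 2), 4OHT against ICI (279; 168) and vehicle against 0 h (754; 0). Chance in how these arrays were divided is argued against for these counts. A share of 1 of 35 is the smallest these splits can give, and it was not adjusted for the number of comparisons. The splits cannot address chance between cultures, since the labels do not say whether replicates were separate cultures. For PEO4 ICI 2 of 35 splits gave 19 or more (highest other 28), so chance cannot be excluded. Any split matches a count of 0, so the 35 of 35 found for such counts could not decide anything. These were ICI+E2 against ICI in PEO1 (highest other 0) and PEO4 (39), and 4OHT+E2 against 4OHT in PEO1 (174). The splits with 39 and 174 genes, far above the real counts of 0, point to some structure among these arrays other than the groups compared. On the first axis of the residuals PEO1 4OHT B (8.5) and 4OHT+E2 D (8.4) stood apart from 4OHT C (-6.2) and 4OHT+E2 A (-6.1). In PEO4 ICI replicate 1 scored 20.8. Whether these arrays made up those splits was not tested.

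For differences between lines 100 draws were made. For ICI 12 genes passed, with 1 draw as large, the real one, and at most 7 genes in any other. Draws that mixed the arrays of both lines removed the drug response from both. They ask whether either line responded, not whether the lines responded alike. Among 8 draws that kept 1 line as labelled 0 were as large, but these do not hold equal responses either. Chance thus stays open for the count of genes that differ between the lines. PEO1 arrays enter that count too, so it does not settle the PEO4 ICI count or the PEO4 median above, for which chance stays open. For E2 (59, 5 draws, highest other 258) and 4OHT (151, 5 draws, highest other 867) it cannot be excluded by this count. In both, the 4 other draws as large were among 8 that kept 1 line as labelled, so they still held that line's drug response; draws that mixed both lines gave at most 3 and 2 genes.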

How the results depend on the processing

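Leaving out the outlying PEO4 arrays together was chosen after the results were seen. Counts that moved by more than 1.5 times under an alternative are given here. With array weights they were stronger for the E2 difference (112), ICI difference (747), 4OHT difference (473), PEO1 ICI (33), PEO1 ICI+E2 against ICI (3) and, in PEO4, E2 (512), ICI (2150), 4OHT (1977), ICI+E2 against E2 (614), 4OHT+E2 against E2 (1474), ICI+E2 against ICI (1743), 4OHT+E2 against 4OHT (79), 4OHT against ICI (2367) and vehicle against 0 h (1617). With only the compared groups they were weaker for PEO1 E2 (159), ICI (8), 4OHT (249), 4OHT+E2 against E2 (497) and 4OHT against ICI (107), and for PEO4 ICI (0), 4OHT+E2 against 4OHT (0) and 4OHT against ICI (82), and stronger for PEO4 4OHT (1033). Without PEO4 0 h replicate 4 and ICI replicate 1 they were stronger for PEO4 E2 (400), 4OHT (1055), ICI+E2 against E2 (407), 4OHT+E2 against 4OHT (32) and the 4OHT difference (294), and weaker for PEO4 ICI (9). PEO1 ICI+E2 against ICI rose from 0 to 1 with a trend and robust variance, 2 with dim genes left out and 2 with the replicate block. Without dim genes PEO4 ICI gave 1, 4OHT+E2 against 4OHT 4 and the lines' levels 231; with the block PEO4 ICI gave 46, and over all probe sets the levels gave 621. The E2 overlap moved to 52 higher and 6 lower at an adjusted p under 0.01 and to 159 and 32 at an unadjusted p under 0.01. With an estimated correlation 47 of 89 list calls and 17 of 35 E2-set calls were made. Leaving out 1 array gave ranges of 42 to 56 for the E2 difference, 8 to 47 for ICI and 77 to 198 for 4OHT. In PEO1 they were 176 to 243 for E2, 8 to 14 for ICI, 384 to 884 for 4OHT, 230 to 266 for ICI+E2 against E2, 951 to 2079 for 4OHT+E2 against E2, 0 to 1 for ICI+E2 against ICI, 0 to 5 for 4OHT+E2 against 4OHT, 220 to 608 for 4OHT against ICI and 585 to 874 for vehicle against 0 h. In PEO4 they were 185 to 206 for E2, 1 to 847 for ICI, 418 to 582 for 4OHT, 155 to 219 for ICI+E2 against E2, 528 to 717 for 4OHT+E2 against E2, 0 to 459 for ICI+E2 against ICI, 4 to 30 for 4OHT+E2 against 4OHT, 163 to 552 for 4OHT against ICI and 552 to 709 for vehicle against 0 h. Of 679 named gene calls 156 were left out by the filter on dim genes and so not tested in it. Of the others 382 passed in every alternative run gene by gene, apart from leaving out an array, and 0 calls reversed. After quantile normalization 13 of 89 called list medians moved by more than 1.5 times and 0 changed sign. The cause was not tested.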

Other observations

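The heat shock genes and single genes in this part were picked after the results were seen, while the set tests were planned. The medians against vehicle were added later. HSPA6 stood apart from the other heat shock genes examined. It rose by 1.63 ± 0.18 in PEO1 and 1.67 ± 0.14 in PEO4 with 4OHT, while 9 other heat shock genes ranged from -0.23 to 0.01 in PEO1 and from -0.28 to 0.06 in PEO4, with 0 and 1 called (HSPA1L, -0.28 ± 0.07). In 4OHT+E2 against E2 the same 9 ranged from -0.11 to 0.04 (1 called, HSPD1, -0.09 ± 0.03) and from -0.09 to 0.16 (1 called, DNAJB1, 0.16 ± 0.05). FOXA1, which opens chromatin for the estrogen receptor, was 0.56 ± 0.08 higher in PEO1 and 0.55 ± 0.07 higher in PEO4 with 4OHT+E2 than with E2; with 4OHT alone it rose in PEO1 (0.36 ± 0.08) and not past the threshold in PEO4 (0.06 ± 0.07, adjusted p = 0.729). SNAI2, a repressor linked to epithelial to mesenchymal transition, rose with 4OHT in PEO1 (0.37 ± 0.08) and PEO4 (0.78 ± 0.13). IGFBP1 rose with 4OHT in PEO4 (0.62 ± 0.12), as did INSIG1, a brake on sterol synthesis (0.57 ± 0.09). Neither passed in PEO1 (0.20 ± 0.08 for IGFBP1 and 0.23 ± 0.08 for INSIG1). TXNIP, a thioredoxin inhibitor, fell with 4OHT by 0.41 ± 0.05 in PEO1 and 0.44 ± 0.04 in PEO4.

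Genes that E2 raised in PEO4 had a median of -0.062 in PEO1 with ICI alone (9 of 199 called lower and 0 higher, adjusted p = 9.12e-15, and 0.00458 with an estimated correlation). The reverse set, genes that E2 raised in PEO1, had 0.063 in PEO4 with ICI (adjusted p = 0.0148, and 0.561 with an estimated correlation) and 0.072 with 4OHT (adjusted p = 2.98e-08, and 0.149 with an estimated correlation). With 4OHT+E2, set against vehicle, those medians were 0.01 in PEO1 and 0.125 in PEO4.

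RNA quality differed between arrays of PEO4. ACTB 3' minus 5' was 3.41 on ICI replicate 1 and 2.28 on 0 h replicate 4, and GAPDH gave 1.74 and 0.86 on them against 0.12 or less on every other array. Their weights in the weighted fit were 0.128 and 0.208. The other ICI arrays had 0.439, 6.33 and 0.501, so weighted PEO4 ICI values rest mostly on replicate 3. In PEO1 the ACTB values lay between -0.25 and 0.14.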
